A study of Phaeodactylum tricornutum with 2 samples.

How the data were processed

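The 2 analysed 10x Genomics Chromium libraries came from *Phaeodactylum tricornutum*, 1 from silicified, oval cells and 1 from non-silicified, fusiform cells. Per the labels' protocols, nuclear suspensions were loaded on Chromium Chip B, polyadenylated RNA was reverse transcribed with barcoded oligo-dT primers, and the amplified, fragmented cDNA was sequenced as paired ends. The authors deposited, per library, a matrix of UMI counts per gene and barcode, not normalized. Per the file headers, the count matrices were written by software version 3.0.2 in the 10x format, while the submitters' processing notes name Cell Ranger 2.1.1 and the mouse build mm10. The features carry *P. tricornutum* gene identifiers (Phatr3), so the build in the notes does not describe them. The *P. tricornutum* genome build, annotation release and strand setting are not given in the sources used here, and reads of overlapping or antisense genes cannot be told apart from these files.

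Each matrix has 12390 features and 6794880 barcodes, the size of a whole barcode list, so barcodes holding RNA had to be called. The threshold was the 99th percentile of UMI totals among the 3000 largest barcodes divided by 10, fixed before the data were examined. UMIs were summed over called barcodes per library, divided by the library total over all features and given as CPM with exact Poisson intervals. The ratio of the libraries has an exact (Clopper-Pearson) interval from the split of both counts. Genes needed at least 100 UMIs summed over both libraries. A count of 0 was set to 3 counts to size a ratio, and the text then gives the limit of its interval. With 1 library per group there is no spread between replicates, so no p-value, standard error or false discovery rate was computed, genes are counted by size of ratio only, and the ratios compare these libraries rather than the conditions. These intervals cover counting error only.

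The features file names 790 features. RefSeq assembly ASM15095v2 was matched by the number in the identifier for 9052 features and gave 52 further names. Where both named a gene, 499 of 513 names were the same apart from case. As that table holds no product descriptions, gene lists were matched on symbols alone, and only 700 of the 8989 measured genes have one. Of 33 lists fixed before the data were examined, 24 had at least 3 measured genes. The transposon list matched 1 carbonic anhydrase alone. The lists of vacuolar proton pumps, fatty acid oxidation, plastid-encoded and mitochondrion-encoded genes matched no measured gene and are not analysed here. Another 9 lists were added after the data were seen. Symbol matching put some genes in lists they may not belong to, such as the adaptor subunits in the phosphate list, and left other genes out. A list's median log2 ratio was ranked among 10000 random lists of the same size matched on expression, but not on having a symbol. Of the 700 measured genes with a symbol, 40 were at least 2-fold higher and 43 at least 2-fold lower in the silicified library. Among all 8989 measured genes these counts were 712 and 344. A low percentile can therefore partly reflect that list members have a symbol, which was not tested.

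Named genes follow a rule set before the data were examined. It takes the 10 named genes with the highest and the 10 with the lowest ratio, ranked by the interval bound nearest to no difference, the top 2 in each direction with or without a name, up to 2 members per list and direction among those at least 1.5-fold apart, and the 5 most abundant genes of each library. A symbol stood in for the annotated product that the rule asks for. Genes named outside this rule (HSP90, HSP70_2, HSP70A, BIP, PCNA, PTSLC4-4, LHCR8, LHCR10, SIT3, SIT4, SIT1, members of lists with fewer than 3 measured genes, and those in the closing section) were chosen after their values were seen.

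Barcodes were clustered per library with leidenalg 0.10.2 at resolution 0.5 on a graph of 15 neighbours from 30 principal components of 2000 variable genes, each seen in at least 20 barcodes, of log-normalised counts. For shares of barcodes with a UMI, barcodes were thinned to 36 UMIs, with exact binomial intervals. Doublets were kept. Scrublet, in scanpy 1.11.5, marked 0 of 73399 and 0 of 74567 barcodes, so it did not work on these data. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and, for TMM factors, edgeR 4.0.16 in R 4.3.3.

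The ratio steps were tested on simulated counts for this comparison, in which 200 of the genes were changed. Of 9014 simulated genes past the filter, 95.2% had an interval holding the true ratio. All measured 3-fold and 4-fold planted changes outside the planted chromosome were counted as at least 2-fold, and 1 of 8515 unchanged genes was. Apart from the planted changes, both simulated libraries were Poisson draws from 1 shared profile, without variation between cultures or handling. The 1 of 8515 therefore covers counting error only and is no rate of false calls for the real libraries. A list of 20 genes planted at 2-fold reached percentile 100.0, and a chromosome planted at 1.5-fold was recovered at 1.50-fold. Alternatives tried were fixed minimums of 200 and 500 UMIs per barcode, 10000 expected barcodes, all barcodes, TMM, the median of gene ratios, the total without the 50 most abundant genes, equal weight per barcode, gene filters of 20 and 500 UMIs, subtraction of 10% free RNA, Leiden resolution 1.0, joint clustering and unthinned shares. Chosen after seeing the data were barcodes under, or at or over, 1.5 times the median, the total without ribosomal RNA, genes with a RefSeq location only, subtraction of chromosome medians, redrawn counts, and clusters from 1 of 2 random parts of each barcode's UMIs.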

Results

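The study profiled *Phaeodactylum tricornutum*, a marine diatom, by droplet sequencing of nuclear suspensions with unique molecular identifiers (UMIs). One library came from genetically modified, silicified cells of oval shape and 1 from wild-type, non-silicified cells of fusiform (spindle) shape. Both carry the same strain name, CCAP 1055/1. The series' aim is to compare the physiological state of the 2 cell forms. Because each group has 1 library, no difference below has a replicate check, and the intervals of levels, ratios and shares are 95% exact intervals that cover counting error only.

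The silicified library held 7083198 UMIs and the non-silicified library 9618279 UMIs. Calling barcodes at the 99th percentile of the 3000 largest barcodes divided by 10 gave thresholds of 24.7 and 35.4 UMIs, and kept 73399 barcodes in the silicified library and 74567 in the non-silicified library. These barcodes held 94.0% and 94.1% of all UMIs. The median barcode had 89 UMIs and 77 genes in the silicified library, against 118 UMIs and 97 genes in the non-silicified library. The barcodes formed 1 narrow main peak in each library, with quartiles of 81 and 98 UMIs in the silicified and of 106 and 133 UMIs in the non-silicified library. The silicified library also had a small rise below it, with 104 barcodes at 38 UMIs against 57 at 25 and 43 at 53 UMIs. Only 1 silicified and 2 non-silicified barcodes reached 500 UMIs. Droplets that held free RNA alone would also form such a peak, so these counts do not show whether a called barcode held a cell, a nucleus or free RNA, and called barcodes are not counted as cells. The comparison below therefore rests on UMIs summed over all called barcodes, 6658096 in the silicified and 9055019 in the non-silicified library.

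**Figure D1:**
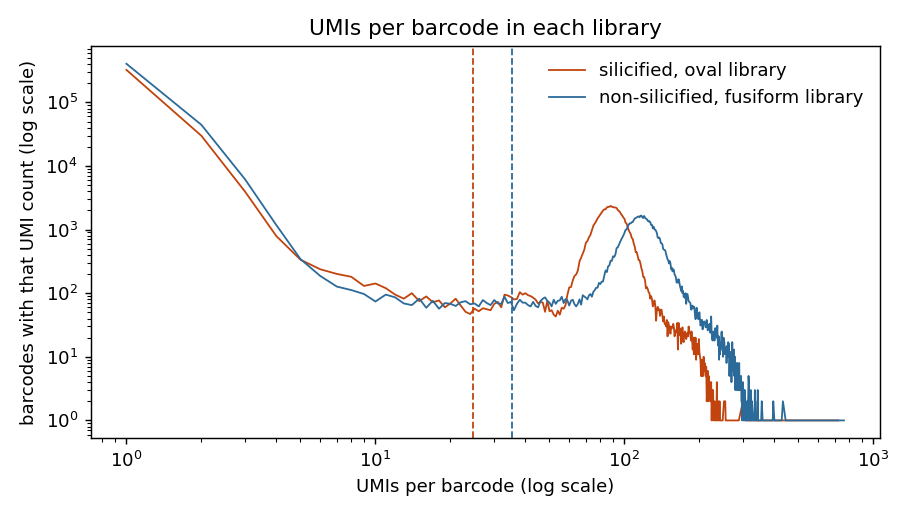
Number of barcodes (vertical axis, log scale) at each UMI count per barcode (horizontal axis, log scale) in the silicified library (orange) and the non-silicified library (blue), with the barcode threshold of each as a dashed line. Each library has 1 main peak, around medians of 89 and 118 UMIs, and few barcodes above it. The silicified library also has a small rise near 38 UMIs.

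The first question was which genes differ in level between the libraries of silicified oval and non-silicified fusiform cells. Small heat shock proteins, chaperones that bind unfolding proteins, stood far higher in the silicified library. HSP20C reached 227 CPM (UMI counts scaled to a library total of 1000000; 216 to 239) against 27.1 CPM (23.8 to 30.7), an 8.39-fold ratio (7.33 to 9.65). HSP20 was 6.76-fold higher, HSP20A 4.0-fold and HSP20B 3.84-fold. In the other direction, 22 of 34 light-harvesting genes (fucoxanthin chlorophyll proteins of the antenna), 9 of 12 histones and 10 of 13 DNA replication genes had a lower level in the silicified library, most of them within 2-fold for light harvesting and DNA replication. LHCF15, the feature with the most UMIs in the non-silicified library, had 39434 CPM there (39304 to 39563) and 15810 CPM (15715 to 15906) in the silicified library, 2.49-fold lower (2.48 to 2.51).

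Among 8989 genes with at least 100 UMIs over both libraries, 712 were at least 2-fold higher in the silicified library and 344 at least 2-fold lower, while 88.3% lay within 2-fold. At least 4-fold differences were found for 152 higher and 34 lower genes. The median log2 ratio was 0.08. TMM scaling lowered every log2 ratio by 0.12 and gave 545 higher and 472 lower genes, and leaving the 50 most abundant genes out of the total gave 538 higher and 477 lower genes. With the median of gene ratios the counts were 586 and 433.

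The widest ratios of all belonged to genes without a name. Phatr3_EG00200 had 5882 UMIs in the silicified library and 4 in the non-silicified library, a 2000-fold ratio with a counting interval of 781 to 7342. Phatr3_EG02278 was 71.3-fold higher (56.6 to 91.0). Phatr3_J11423 had 2 UMIs in the silicified and 2011 in the non-silicified library, a 739-fold lower level (204 to 6109). Phatr3_J49977 had 0 against 232 UMIs, and the interval of its ratio starts at 45.9-fold lower. With all barcodes, the log2 ratio went from 10.97 to 9.59 for Phatr3_EG00200 and from -9.53 to -8.29 for Phatr3_J11423, so such sizes rest on a few UMIs.

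Outside the small heat shock proteins, the named genes with the highest ratios were single genes that symbol matching placed in no fixed list. By function, PTSLC4-2, PTBZIP16, LPAAT and CK1 Phatr3_J51110 would belong to the carbon concentration, transcription factor, triacylglycerol and kinase lists. The values of those lists below leave them out. PTSLC4-2, an SLC4-type bicarbonate transporter (identifier Phatr3_Jdraft1806), had 846 CPM (824 to 869) in the silicified and 68.4 CPM (63.1 to 74.0) in the non-silicified library, 12.4-fold higher (11.4 to 13.5). Its paralogue PTSLC4-4 had a log2 ratio of -0.74, so the 4 measured SLC4 genes did not move together (median log2 ratio 0.27). PTBZIP16, a basic leucine zipper transcription factor, was 9.49-fold higher (8.05 to 11.3), MS 7.17-fold (6.48 to 7.95) and PT-MAD1 6.15-fold (5.55 to 6.82). LPAAT, a lysophosphatidic acid acyltransferase of glycerolipid synthesis, was 3.53-fold higher (3.11 to 4.01), and CK1 Phatr3_J51110, a casein kinase 1, was 3.25-fold higher (2.94 to 3.60).

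The named genes with the lowest ratios, ranked by the interval bound nearest to no difference, were spread over several lists. Symbol matching placed SUFD, TRD6 and VPPIB in no fixed list, so no list value below includes them. HEME, uroporphyrinogen decarboxylase of the tetrapyrrole pathway, was 4.49-fold lower in the silicified library (3.59 to 5.69). The antenna gene LHCF12 was 3.75-fold lower (3.20 to 4.41). FBAC5, a fructose-bisphosphate aldolase, had 1140 CPM in the silicified and 3946 CPM in the non-silicified library, 3.46-fold lower (3.38 to 3.55). SUFD, of iron-sulphur cluster assembly, was 3.38-fold lower (3.0 to 3.82), the DNA polymerase alpha gene POLA 3.36-fold (2.96 to 3.82), the histone H2A-3A Phatr3_J34798 3.29-fold (2.61 to 4.20) and the fatty acid desaturase PTD12 2.97-fold (2.55 to 3.49). TRD6 and VPPIB were 3.54-fold and 2.83-fold lower.

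**Figure D2:**
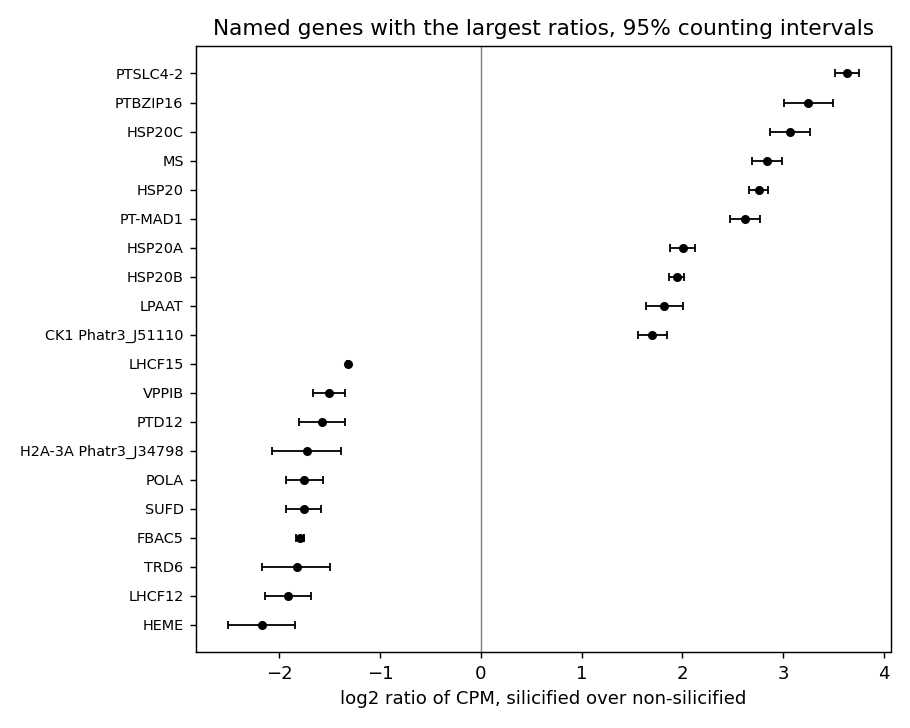
Log2 ratio of CPM, silicified over non-silicified (horizontal axis), for 10 higher and 10 lower named genes, with 95% counting intervals as bars. The genes were picked by the interval bound nearest to no difference, so some named genes with lower ratios but wider intervals, such as CYCB2 and HSF2, are not shown. PTSLC4-2 is highest at 12.4-fold and HEME lowest at 4.49-fold lower.

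Chaperones as a list of 18 measured genes had a median log2 ratio of 0.69, at percentile 99.9 of 10000 random lists matched on expression. The interval of this median over these genes was 0.11 to 1.73. Random lists were not matched on having a symbol, so low percentiles of the lists below can partly reflect that. Of the 18 chaperone genes, 6 were at least 2-fold higher and 0 at least 2-fold lower. The higher ones were the 4 HSP20 genes, HSP90 (log2 ratio 1.73) and HSP70_2 (1.02), while the abundant HSP70A stood at -0.30 and the endoplasmic reticulum chaperone BIP at 0.99. The 4 HSP20 genes alone, a list added after the data were seen, had a median of 2.38. Ribosomal RNA took 8.36% of the UMIs in the silicified and 7.31% in the non-silicified library.

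Histones had a median log2 ratio of -1.05 over 12 measured genes, below all 10000 matched random lists (percentile 0). The interval of this median over these genes, -1.28 to 0.03, reached past 0. Of them, 7 were at least 2-fold lower, among them H2A-M2 at 2.43-fold lower (2.21 to 2.66). In the other direction, H3-1C Phatr3_J50695 stood at 2.06-fold higher and the replacement histone H3.3 at 1.64-fold higher (log2 ratios of 1.04 and 0.72, and of 0.92 and 0.13 once the medians of their chromosomes were subtracted). As these 2 are the most abundant histones, the list as a whole took more of the UMIs in the silicified library (0.283%) than in the non-silicified library (0.241%), opposite to its median. In the few barcodes with at least 200 UMIs the histone median was 0.51, but over 3 genes only, whose median in all called barcodes was 0.72. Copies of the same histone are nearly identical, so their separate counts are uncertain. The 13 measured DNA replication genes had a median of -0.68 (percentile 0, interval over these genes -1.23 to 0.18). Among them, MCM4 of the replicative helicase was 2.52-fold lower (1.96 to 3.28) and the sliding clamp PCNA stood at a log2 ratio of -0.91. Of the 13 genes, 4 were at least 2-fold lower and 0 higher. Over 39 cell cycle genes the median was -0.09 (percentile 3.56), with the cyclin CYCB2 3.24-fold lower (2.37 to 4.49), SMC2 of condensin 2.05-fold lower and DSCYC8 2.77-fold higher. CYCP2 was 1.83-fold higher, but at a log2 ratio of -0.065 once the median of its chromosome was subtracted. The 12 kinesins, an added list, had a median of -0.41.

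Light-harvesting genes had a median log2 ratio of -0.41 over 34 measured members (percentile 0). The interval of this median over these genes, -0.55 to 0.06, reached past 0. Of these genes, 2 were at least 2-fold lower and 4 at least 2-fold higher. The lower ones were LHCF15 and LHCF12, and LHCF5 was 1.39-fold lower (1.38 to 1.41). The higher ones were LHCX4 at 3.23-fold (2.57 to 4.10), LHCR5 at 2.63-fold (2.08 to 3.35), LHCR8 (log2 ratio 1.05, from 535 and 351 UMIs) and LHCR10 (1.0, from 1609 and 1092 UMIs). Together the list took 7.05% of the UMIs in the silicified and 10.7% in the non-silicified library. The LHCF genes alone had a median of -0.48 and the LHCR genes -0.17, both as added lists. Reads of LHCF copies with near-identical sequence may be shared among them. Pigment synthesis genes had a median of -0.37 over 28 genes (percentile 0, interval over these genes -0.59 to -0.19). HEME and the zeaxanthin epoxidase ZEP1 (2.06-fold lower) were past 2-fold, and no gene was 2-fold higher. In barcodes with at least 200 UMIs this median was 0.051 over 5 genes, whose median in all called barcodes was -0.24. The 6 photosystem and electron transport genes had a median of -0.39 (percentile 4.58, interval over these genes -0.98 to 0.49). Among them, cytochrome c6, PETJ, was 1.98-fold lower and PSBU 1.56-fold lower.

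In central carbon metabolism, 34 glycolysis genes had a median log2 ratio of -0.26 (percentile 0.03, interval over these genes -0.48 to 0.18). FBAC5 and PGAM_4 (2.39-fold lower) were past 2-fold, and GAPC4 stood at 1.92-fold higher. The Calvin cycle stood at -0.06 over 11 genes and the tricarboxylic acid cycle at -0.02 over 5, with SDH2 1.67-fold lower. The log2 ratio of SDH2 was -0.74, and -0.26 once the median of its chromosome was subtracted. Carbon concentration genes had a median of 0.26 over 6 genes, with pyruvate carboxylase, PYC1, 1.89-fold higher. The 6 triose phosphate transporters, an added list, had a median of -0.59. Fatty acid synthesis had a median of -0.19 over 24 genes (percentile 2.0), with ACS3 2.16-fold and FABZ 2.1-fold higher, and PTD12 and FAD2 (2.5-fold) lower. The 6 triacylglycerol genes had a median of 0.01, a sign that depends on the scaling, with DGAT2D 1.63-fold higher.

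Iron response genes split. ISIP1, an iron starvation-induced protein, was 2.78-fold higher (2.73 to 2.84) at 4829 CPM against 1735 CPM, while ISIP3 was 2.57-fold lower (2.27 to 2.92) and the ferric reductase FRE3 2.15-fold lower (1.99 to 2.32). The 9 measured members had a median of -0.41 (percentile 1.31, interval over these genes -1.36 to 0.18). Nitrogen genes had a median of -0.22 over 8, with the glutamine synthetase GLNA 2.01-fold lower and the carbamoyl phosphate synthetase CPS-II 2.02-fold higher. Of the silicon-associated symbols, SIT4 was the only one with 100 UMIs, at a log2 ratio of -0.46 from 153 and 287 UMIs. SIT3 had 20 and 7 UMIs, and both SIT1 genes had 0 in each library.

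The 4 measured ribosomal protein genes had a median log2 ratio of 0.73 (percentile 96.0), with RPL14 at 1.97-fold and RPS19 at 1.68-fold higher. Proteasome and ubiquitin genes had a median of 0.32 over 14 genes (percentile 85.9), with UBI3 2.15-fold and RPN7 1.83-fold higher. The RPN subunits alone, an added list, stood at 0.27, as did the 8 signalosome subunits at 0.28. Transcription factors had a median of 0.60 over 5 genes (interval over these genes -1.69 to 1.32), with the photoreceptor DPH1 2.5-fold higher. HSF3 was 1.54-fold higher (1.47 to 1.62, from 3488 and 3077 UMIs) and HSF2 3.23-fold lower (from 36 and 158 UMIs). Oxidative stress genes stood at -0.01 over 9, also of either sign by scaling, with CAT2 2.69-fold higher. Amino acid synthesis stood at -0.07 over 7 with GDCH 1.82-fold higher, and the cytoskeleton at 0.16 over 12 with myoA2 2.1-fold higher. Other lists whose sign depends on the scaling were vesicle traffic (0.06 over 24 genes, RAB5A 1.80-fold higher), the phosphate list (0.07 over 12, of which 11 are adaptor complex subunits, with AP3mu 2.77-fold higher), those adaptor subunits alone as an added list (0.07) and cell wall glycans (0.09 over 3, UGP/PGM 2.15-fold lower). Lists with fewer than 3 measured genes are given singly. These were ATP1 (-0.18) and AOX1 (0.14) of the respiratory chain, EIF6 (0.53) and EF-1 (0.33) of translation and CDPK1 (-0.39) of the kinases. The transposon list matched only the symbol PTCA2, a carbonic anhydrase already counted under carbon concentration, so transposons are not analysed here.

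**Figure D3:**
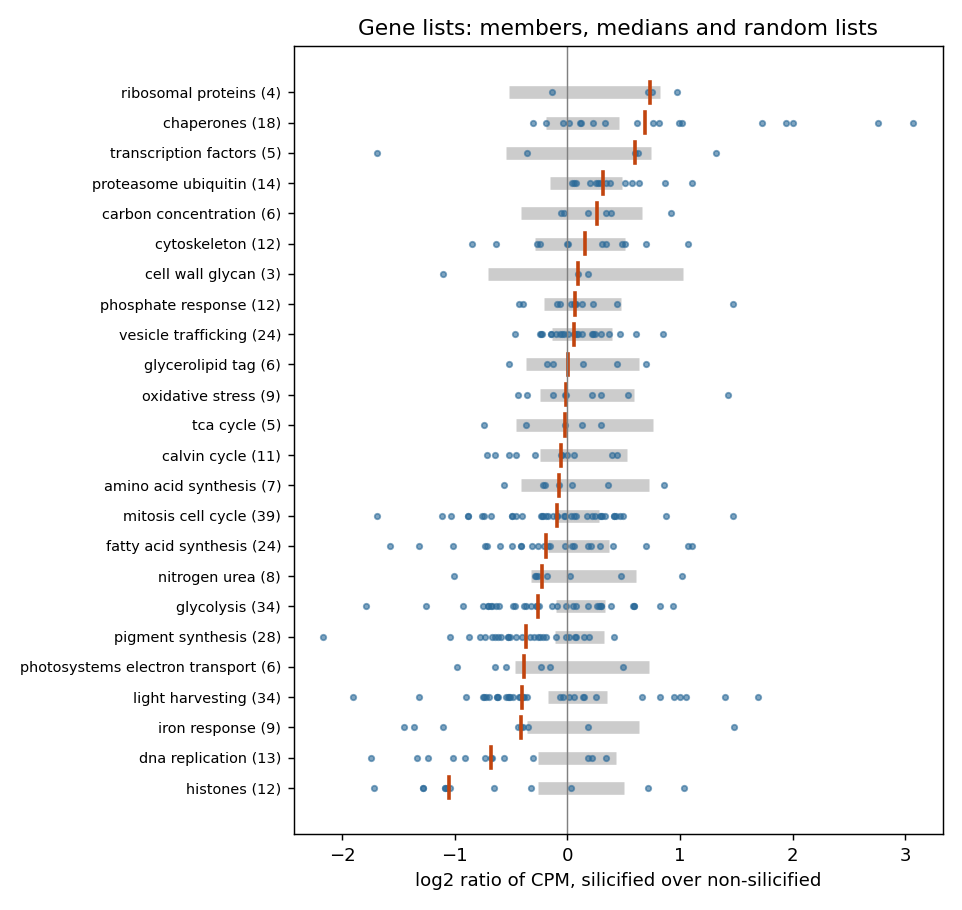
Log2 ratio of CPM, silicified over non-silicified (horizontal axis), of each measured member (blue points) of the lists with at least 3 measured members, list median (orange) and the central 95% of medians of 10000 matched random lists (grey). Histones at -1.05 and DNA replication at -0.68 lie below the grey range. Light harvesting, pigment synthesis, glycolysis, fatty acid synthesis and iron response also lie below it. Only chaperones, at 0.69, lie above it. The random lists were not matched on having a symbol.

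Ratios also grouped by chromosome, as assigned by RefSeq assembly ASM15095v2 to genes with matching identifiers. Over 7358 genes on 32 chromosomes, the median log2 ratio was 0.94 on chromosome 24 (99 genes), 0.60 on chromosome 2 (491 genes), 0.58 on chromosome 12 (261 genes) and 0.51 on chromosome 17 (199 genes). It was -0.49 on chromosome 30 and -0.47 on chromosome 21. When genes were shuffled over chromosomes 1000 times within expression bins, 11 chromosomes lay outside every shuffle. The 4 higher chromosomes held 14.3% of the genes and 36.6% of those at least 2-fold higher. Of the 7371 measured genes with any RefSeq location, 557 were at least 2-fold higher and 291 lower before, and 385 and 302 after, subtraction of chromosome medians. Over the members with a location, subtraction took the light-harvesting median from -0.49 to -0.70 (24 genes), the pigment synthesis median from -0.53 to -0.63 (19 genes) and the LHCF median from -0.498 to -0.72 (16 genes). It took the log2 ratio of LHCF5 from -0.48 to -1.42, of GAPC4 from 0.94 to 0.34, of GDCH from 0.86 to 0.26, of RAB5A from 0.84 to 0.24, of DGAT2D from 0.70 to 0.10 and of AP3mu from 1.47 to 0.87.

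**Figure D4:**
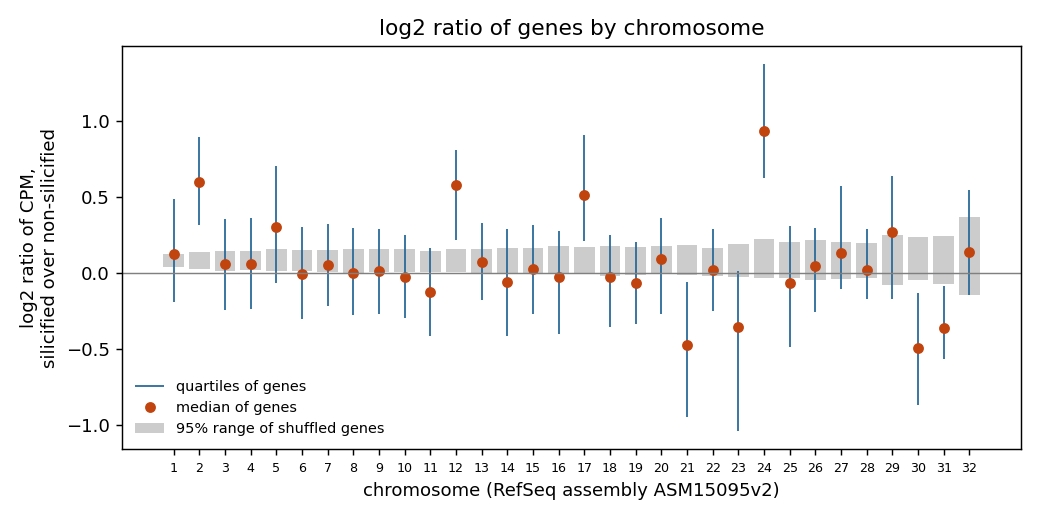
Log2 ratio of CPM, silicified over non-silicified (vertical axis), by chromosome (horizontal axis), with the median (orange point) and quartiles (blue line) of its genes and the central 95% of medians of shuffled genes (grey). Chromosomes 24, 2, 12 and 17 lie furthest above the grey range at 0.94, 0.60, 0.58 and 0.51. Chromosomes 5 (0.31) and 29 (0.27) also lie above it. Several others lie below it, the lowest being 30 (-0.49) and 21 (-0.47).

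The second question was whether cells within a library fall into kinds, which could be read only on called barcodes that are not shown to be cells. Leiden clustering gave 63 clusters of at least 50 barcodes in the silicified library and 53 in the non-silicified library. Counts redrawn at random from the pooled profile of each library, at each barcode's own UMI count, gave 63 clusters in both, so a number of clusters alone does not show kinds of barcodes. In a test chosen after the data were seen, the UMIs of each barcode were split at random into 2 parts, clusters were made from the first part, and their 10 leading genes were read in the other part. Over 81 silicified clusters the leading genes were a median of 6.31-fold higher inside a cluster than outside it in the part used for clustering and 1.23-fold in the other part, and over 85 non-silicified clusters 6.77-fold and 1.17-fold. The interval of the ratio in the other part lay above 1 for 54 and 44 of these clusters, against 2 of 99 and 2 of 90 for redrawn counts, and the ratio reached 1.5-fold for 11 and 2 clusters, against 0 and 0. The highest ratio in the other part was 4.17-fold (3.89 to 4.47), in a non-silicified cluster of 2262 barcodes, against at most 1.33-fold for redrawn counts of that library. The clusters thus hold differences beyond sampling of the pooled profile, small in most of them, without showing that they are kinds of cells. Among the clusters made from all UMIs, 2 silicified ones with 267 barcodes together (0.364%) had 3 light-harvesting genes among their 10 leading genes, and no other cluster had 3 of any marker class fixed before the data were examined. No cluster was named, and neither their sizes nor their genes are compared. Of the barcodes under 1.5 times the median UMI count, 2.17% of the silicified and 2.24% of the non-silicified ones departed from the pooled profile by more than 99% of redrawn barcodes, where chance gives 1.00% and 0.99%. Of the barcodes at or over that limit, 4.57% (92 of 2011) and 3.74% (121 of 3238) did, against 0.995% and 1.24% of redrawn ones.

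After every barcode was thinned to 36 UMIs, LHCF15 had a UMI in 43.3% of silicified (43.0 to 43.7) and 76.3% of non-silicified barcodes (76.0 to 76.6), and the unnamed gene Phatr3_J47667 in 39.8% and 60.5%. LHCF5 had a UMI in 36.1% and 47.1%, the 18S ribosomal RNA in 79.0% and 67.5%, and the most abundant 28S ribosomal RNA feature in 69.8% and 71.9%. Thinning left out 752 silicified barcodes (1.02%) and 0 non-silicified barcodes. Because no class of barcodes lacking these transcripts could be told from the rest, these shares cannot be set against a background from free RNA. At a fixed 36 UMIs, such shares also largely follow from a gene's level in the pooled profile, so they are no separate result per barcode. Shares expected from the pooled profile were not computed. The intervals treat barcodes of 1 library as units.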

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

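The tests in this part were all chosen after the results were seen. A signal appeared in barcodes that the comparisons do not use, those below the threshold. The 4 HSP20 genes had 1009 of 425102 UMIs there in the silicified library and 336 of 563260 in the non-silicified library, a 3.98-fold ratio (3.51 to 4.52, counting error only). In the called barcodes they took 0.216% and 0.0436% of the UMIs. The genes were chosen after they were seen higher in called barcodes of these same 2 libraries, so this ratio is no independent check.

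The HSP20 genes stood higher together with a lower median over 12 histones. The histone part covers 9 of the 12 genes and not the most abundant ones, since the summed share of histones in all UMIs was 0.283% in the silicified and 0.241% in the non-silicified library. Scaling does not account for the medians, since under 4 other scalings the lowest HSP20 median was 2.26 on the log2 scale and the highest histone median -1.04. Nor do the chromosome shifts, since after subtracting chromosome medians the HSP20 median was 2.42 and the histone median -1.07. Handling of the cells or the growth stage of each culture cannot be told apart from the silicified form, because there is 1 library per group. The genetic modification, the cell shape and the silicification go together in these libraries and stay open as biological explanations, untested.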

How the results depend on the processing

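Depth per barcode, at medians of 89 and 118 UMIs, and 1 library per group limit these results. No paired analysis was possible because each group has 1 library. Of 74 named genes, 73 kept their direction under every alternative that measured them. The exception was CYCP2, at a log2 ratio of -0.065 after subtraction of its chromosome's median, added after seeing the data. Most named genes were picked by the size of their ratio, and every alternative reused the same libraries. A kept direction was thus largely fixed in advance and is no independent check. Sizes moved more. Log2 ratios lay outside their counting interval for 27 of 74 genes under TMM, 30 of 74 without the 50 most abundant genes, 26 of 58, besides CYCP2, after that subtraction, 31 of 45 in barcodes at or over 1.5 times the median and 19 of 24 at a minimum of 200 UMIs. With CYCP2, 13 genes moved by at least 1.5-fold somewhere. These were LHCF5 (to -1.42), AP3mu (0.87), GAPC4 (0.34), GDCH (0.26), RAB5A (0.24) and DGAT2D (0.10) after that subtraction, VPPIB (-3.72) and Phatr3_J11423 (-2.35) at 200 UMIs, Phatr3_J47667 (-2.45) at 500 UMIs, FAD2 (-0.68) and Phatr3_EG00200 (9.15) in barcodes at or over 1.5 times the median, and Phatr3_EG02278 (6.80) after free RNA subtraction. The counts of genes at least 2-fold higher or lower stayed within 1.5 times the main counts under TMM, the median of gene ratios, the totals without the 50 most abundant genes or without ribosomal RNA, equal weights, all barcodes, 10000 expected barcodes, 10% free RNA subtraction, the filter of 20 UMIs, barcodes under 1.5 times the median, and genes with a RefSeq location. A filter of 500 UMIs gave 366 higher and 172 lower genes among 5258, fewer because fewer genes were tested. Chromosome medians subtracted gave 385 higher genes among the 7371 with a location (557 before subtraction), with medians of -0.70 for light harvesting over 24 genes, -0.63 for pigment synthesis over 19 and -0.72 for LHCF over 16 (-0.49, -0.53 and -0.498 for these genes before). Barcodes at or over 1.5 times the median, added after seeing the data, gave 154 higher and 105 lower genes among 1683, with medians of -0.50 for glycolysis over 16 genes, 0.27 for cell wall glycans over 3, 0.37 for oxidative stress over 5 and -0.065 for histones over 5 (main medians of these genes -0.42, 0.09, -0.01 and -0.33). A minimum of 200 UMIs kept 201 silicified and 1827 non-silicified barcodes, with 54 higher and 87 lower genes among 644, and medians of 0.051 for pigment synthesis over 5 genes and 0.51 for histones over 3, which both changed sign, and -0.65 for LHCR over 8. The main medians of these 5, 3 and 8 genes were -0.24, 0.72 and -0.52, so the histone sign came from the genes left. A minimum of 500 UMIs kept 1 and 2 barcodes, with 0 higher and 1 lower gene. Except for the genes tested, the cause was not tested. In the non-silicified library, Leiden resolution 1.0 gave 81 clusters and clustering on 1 random part of the UMIs 85. Unthinned shares, in the silicified and the non-silicified library, were 96.9% and 95.7% for 18S, 93.2% and 96.7% for 28S, 66.0% and 86.2% for LHCF5, 67.9% and 91.9% for Phatr3_J47667, and 74.4% and 98.5% for LHCF15. Removal of doublets was left without a value, since Scrublet marked 0 barcodes.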

Other observations

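The tests in this part were all chosen after the results were seen. Barcodes with at least 1.5 times the median UMI count (2011 silicified, 3238 non-silicified) differed in their summed profile from the rest, although only 4.57% and 3.74% of them departed singly from the pooled profile by more than 99% of redrawn barcodes. Of 246 genes with at least 3000 UMIs in each library, 23 were at least 1.5-fold higher in these upper barcodes than in the other called barcodes of both libraries. Among them were the iron genes ISIP1 (1.70-fold in the silicified and 1.67-fold in the non-silicified library) and ISIP2A (1.76-fold and 1.67-fold), the acetyl-CoA carboxylase ACC1 (1.87-fold and 1.68-fold), the bicarbonate transporter PTSLC4-4 (1.84-fold and 1.64-fold) and FBAC5 (1.70-fold and 1.67-fold). H3.3 was lower there, at log2 ratios of -0.39 and -0.39.

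Sampling of the same pooled RNA does not account for this, since the spread of these ratios was at least 4.44 times that of redrawn counts in each library. Pairs of droplets sharing a barcode would keep the pooled profile and so do not account for the 23 genes. The ratios correlated between the libraries across genes (Pearson r = 0.93 over 246 genes, which are not independent replicates, against -0.05 for redrawn counts). A candidate explanation is that some upper droplets held a particle with RNA of its own. No biological explanation by group was tested.

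The chromosome medians are a further pattern. Expression level does not account for them, since their SD over chromosomes was 0.30 before and 0.30 after subtracting expression bins, against at most 0.102 in 1000 shuffles. Gene length does not either, with an SD of 0.30 after subtracting length bins. Extra copies of whole chromosomes in the silicified cells are a hypothesis under which both sides of a chromosome shift. Of 7 chromosomes with a median of 0.4 or more on 1 side of the middle gene, 4 (2, 12, 17 and 24) had over 0.3 on the other side, while the other side stood at 0.04 on chromosome 5, 0.01 on 27 and -0.066 on 29, against whole extra copies of these 3. Nor do extra copies in the silicified cells account for chromosomes 21, 30 and 31, which were lower on both sides (-0.41 and -0.58, -0.56 and -0.43, -0.36 and -0.39). A step from 2 to 3 copies would give a log2 ratio of 0.58, near the 0.60, 0.58 and 0.51 of chromosomes 2, 12 and 17 but below the 0.94 of chromosome 24 (95% interval of the median over its 99 genes, 0.85 to 1.11), which such a step alone does not match. For chromosomes 2, 12, 17 and 24, extra copies cannot be told apart from regulation along whole chromosomes, because copy number was not measured. Larger steps, gains or losses of chromosome parts, losses of whole chromosomes and extra copies in the non-silicified cells were not tested and stay open.

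The median was 0.59 for genes before and 0.04 for genes after the middle gene on chromosome 5, -0.97 and -0.02 on chromosome 23, 0.01 and 0.499 on chromosome 27, and 0.53 and -0.066 on chromosome 29. Near the end of chromosome 25, the neighbours Phatr3_J49975, Phatr3_J49976 and Phatr3_J49977 had 0 UMIs in the silicified library against 16, 169 and 232 UMIs in the non-silicified library. The flanking genes Phatr3_J49974 and Phatr3_J49978 were 4.0-fold and 5.11-fold lower. Among all measured genes, 2 had no UMI in the silicified library and 0 had none in the non-silicified library.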
